A study of Mus musculus with 30 samples.

How the data were processed

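RNA of 30 single mouse blastocysts was measured, 1 blastocyst per array. The deposited values were log2 signals of 65956 transcript clusters per array, summarised with RMA in Affymetrix Expression Console on genome build mm10, per the submitters' processing notes; the versions were not given in the sources used here. RMA subtracts background, normalizes across arrays and summarises the probes of a cluster by median polish, so the signals are relative within a cluster and carry no count of molecules. The base of the logarithm was taken from the range of the values and from RMA's own scale, since no label states it. RNA was labelled with the GeneChip WT Pico kit, in which 20 µg of amplified cRNA and 5.5 µg of cDNA entered each labelling, per the labels' protocols. The number of arrays limits the precision of every value. The amplification of so little RNA may add spread between arrays, which single blastocysts do not allow to be separated from spread between embryos.

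Samples were grouped by their titles into 10 GM501 twins, 10 SAGE 1-Step twins and 10 KSOM(aa) controls. The numbers of the twins name the embryo of origin, per the labels, and pair each GM501 twin with its SAGE sister. The pairing was checked on the values: with each gene centred within its medium, Pearson's r across genes between the numbered partners ran from 0.163 to 0.696, and 7 of the 10 GM501 twins correlated best with their own partner. The pair was therefore a block in the comparison of the media. The numbers of the controls name no pair. No 2 of the 30 arrays held identical values, and r between any 2 arrays ran from 0.929 to 0.985 across clusters.

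Clusters were matched to gene symbols through the names listed with them and the gene table of GRCm38.p6, the patch release of mm10. Of the 65956 clusters, 32750 had a listed gene. Of these, 30604 carried 1 distinct symbol, 821 of them updated through the gene ID, and 2146 carried several and were not used for named genes. Gata3 and Ddx3y stood on such clusters and are not reported here. Where several clusters carried 1 gene, the cluster with the highest mean over all arrays was used, which left 30142 genes. Of these, the upper 60% by mean over all 30 arrays were kept, 18087 genes with means of at least 4.8. Sox17 fell below that level and was not analysed here. Clusters without a single named gene went into separate fits.

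Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the genes kept, call at an adjusted p under 0.05). The media were compared within pairs. Each twin group was compared with the controls on those 20 arrays alone. Twins of both media were compared with the controls on 10 pair means, so that no embryo counted as 2. The embryo of origin was tested with limma's F test over the pairs, with medium in the model. The labels call every blastocyst a separate sample but do not say how many matings or culture days they came from, so the p-values measure the spread between these embryos only. Standard errors (SE) are limma's moderated ones.

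Named genes followed a rule fixed before the data were examined, like the groups, tests, gene lists and all settings but those named below as added. In each comparison with controls the rule took the 8 largest rises and 8 largest falls among called genes with at least 8 of 10 arrays on the called side of the controls' median. Up to 4 called members of each list with the smallest p came next, and Cdx2, Pou5f1, Nanog, Sox2 and Gata6 were named whatever their p. Where nothing was called, the 10 genes with the smallest p were named. For the embryo of origin, the rule took the 10 genes with the smallest p and sex-linked genes. Predicted genes, pseudogenes and small RNAs were counted but not named under these rules. Acat3, Mvk, Lss, Hsd17b7, Fasn, Acaca and Srebf2, and Acsl4 in the comparison of GM501 with controls, were named after their values were seen.

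The 30 fixed gene lists covered blastocyst lineages, metabolism, stress responses, the cell cycle, maternal transcripts and markers of other cells. Each list was tested with limma's camera, which compares its genes with all others, at a preset correlation of 0.01 and again with an estimated correlation; adjustment ran over the lists of 1 comparison. Beside it, limma's fry tested whether a list's genes moved, on balance, 1 way, without comparing them with other genes. Each list's median was also ranked among 10000 random lists matched on mean level. A list of markers of oviduct, blood and immune cells had under 3 measured genes and was not tested.

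The spread of single embryos was the root mean square distance of each array to the mean of the others of its group, scaled by the group's size to that expected in a group of 10, and compared by permutation. Co-twin similarity was tested by permuting the pairing, with 100000 resamples. Both comparisons with controls share the 10 control arrays; their correlation and covariance were set beside values simulated without any effect, and were computed again with the controls divided 5 and 5.

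The fits were tested on simulated arrays of 18087 genes with 100 genes changed by a log2 of 1 and 100 by 0.5. A change of 1 was recovered for 83% of genes between media, 78% in GM501 against controls, 75% in SAGE against controls and 75% in both media against controls. The shares for 0.5 were 24%, 22%, 17% and 26%, in the same order, with 7, 5, 5 and 4 false calls.

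Results were computed again, where a setting applied to them, with the mean of all clusters of a gene, no filter and a stricter filter, quantile normalization again, centring each array on its median, eBayes with trend and robust fitting, array weights, a minimum of 1.5-fold, other uses of the sample numbers as a replicate block, each pair left out in turn, and covariates from sex-linked genes (the mean of Eif2s3y, Kdm5d and Uty, and Xist). Twins were divided into sets by their array medians. In pairs 1 to 6 both co-twins lay above the highest control, and pairs 7 to 10 were the others. Pairs 7 to 10 were thus picked for medians nearer the controls, which may itself make their differences from controls smaller. Fits with pairs 7 to 10, pairs 7, 9 and 10, or pairs 1 to 6 alone were added after the data had been seen. So were fits with the array median as a covariate, sex covariates for gene lists and permutations of the pairing within these sets. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.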

Results

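Transcript levels were measured in 30 single mouse blastocysts from B6C3F1 × CD1 matings, each on its own array. Of these, 20 were monozygotic twins from 10 embryos divided at the 2-cell stage. From each embryo, 1 blastomere grew alone in GM501 and its sister alone in SAGE 1-Step, both media made for assisted human reproduction. The other 10 blastocysts were undivided controls grown singly in KSOM(aa), a mouse embryo medium with amino acids. All were lysed at 4 days post coitum after 96 h in culture, with about 40 to 50 cells in a twin and 80 in a control, per the labels. Controls therefore differed from twins in medium, in bisection and in cell number at once, and these cannot be told apart in any comparison with them.

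Array medians were 4.88 ± 0.24 log2 units in GM501 twins, 4.89 ± 0.23 in SAGE twins and 4.64 ± 0.029 in controls (mean ± SD, n = 10 each). The sets defined by these medians lay at 5.01 ± 0.15 in pairs 1 to 6 (SD, 12 arrays) and 4.69 ± 0.18 in pairs 7 to 10 (SD, 8 arrays). Controls entered the rule for the sets, so this gap in median was built in. So was the closeness of pairs 7 to 10 to controls in median. Along the first principal component, with 39.6% of the variance, pairs 1 to 6 lay at -57.1 ± 17.1, pairs 7 to 10 at 38.5 ± 22.7 and controls at 37.7 ± 5.24 (SD). The SAGE twin of pair 8 stood apart from its set, with a median of 5.12 and a first component of -15.4. No label names a batch, and all controls lay with pairs 7 to 10. In comparisons with controls, main values of pairs 7 to 10 alone are therefore set beside those of all 10 pairs, as are counts of the named genes called in them. The number of arrays limits the precision of all values.

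**Figure D1:**
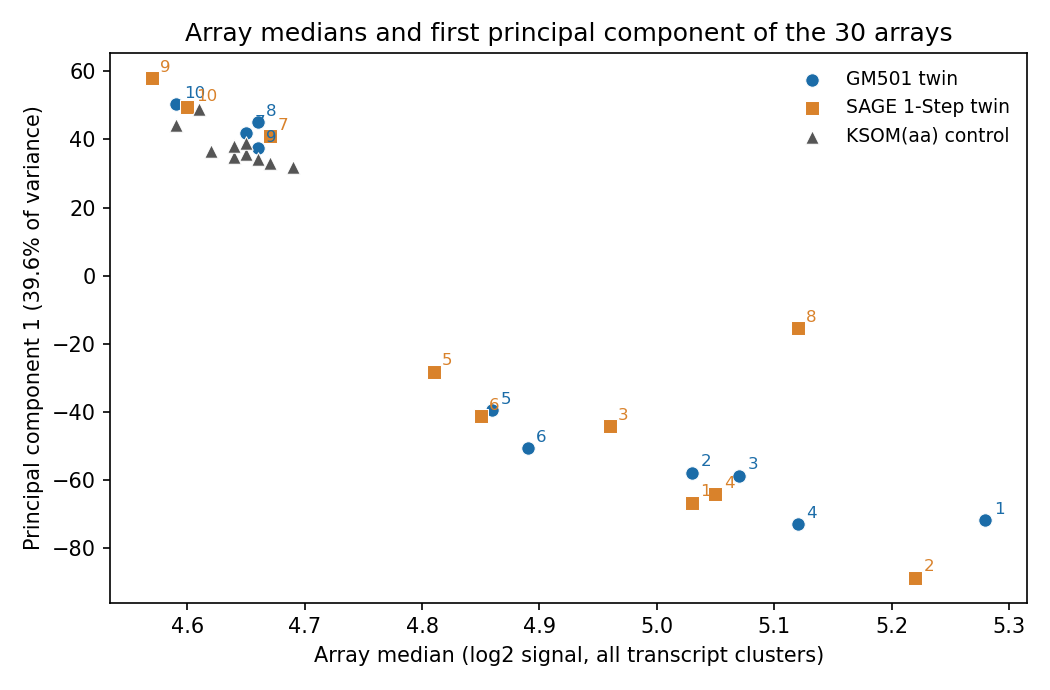
Array median over all transcript clusters (log2 signal, horizontal) against the first principal component (39.6% of variance, vertical) for the 30 arrays, with twins numbered by pair. Both twins of pairs 1 to 6 lie at or below -28.2 on the vertical axis, whereas controls and all twins of pairs 7 to 10 but the SAGE twin of pair 8 lie above 0.

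The first comparison asked whether the medium alone changed transcript levels, since co-twins share a genome and differ in medium. No gene passed the test between GM501 and SAGE twins. Smim22, at chromosome 16, 5007288 to 5008309 (GRCm38), had the smallest p, with a log2 difference of 0.75 ± 0.12 (SE, 10 pairs), positive in 10 of 10 pairs. Clec2f, a C-type lectin gene, differed by 1.34 ± 0.24 and was higher in GM501 in 9 of 10 pairs. Hpse, which encodes heparanase, differed by -1.45 ± 0.26 and was lower in 10 of 10, and the adjusted p of all 3 genes was 0.584. Zfp930, Zfp35, Plk3, Npl, Nceh1, Polr1a and Jph1 came next, with differences from -0.81 ± 0.18 for Zfp35 to 1.11 ± 0.25 for Npl and an adjusted p of 0.796 each.

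Among the lineage regulators, Cdx2 of the trophectoderm differed by 0.24 ± 0.16 and Gata6 of the primitive endoderm by 0.33 ± 0.28 (SE, 10 pairs). The pluripotency factors Pou5f1, Nanog and Sox2 differed by 0.46 ± 0.23, 0.50 ± 0.48 and 0.47 ± 0.23. Each was higher in GM501 in 6 or 7 of 10 pairs, at an adjusted p of 1. Within pairs 7 to 10 the differences of Nanog and Sox2 were 1.95 ± 0.49 and 1.18 ± 0.29, at an adjusted p of 0.832.

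As lists, 5 of the fixed gene groups shifted between media at the preset correlation, and none with an estimated correlation. Epiblast and inner cell mass genes were higher in GM501, with a median of 0.20, 16 of 19 members positive and an adjusted p of 0.000598; adjusted p = 0.696 with an estimated correlation. Their median was 0.012 in pairs 1 to 6 (adjusted p = 0.522) and 0.48 in pairs 7 to 10 (adjusted p = 5.22e-05; adjusted p = 0.929 with an estimated correlation), and 0.20 without pair 8 of the latter (adjusted p = 0.0585). Genes of ribosome biogenesis had a median of 0.10 with 25 of 28 members positive (adjusted p = 0.00597; adjusted p = 0.936 with an estimated correlation), -0.11 in pairs 1 to 6, 0.46 in pairs 7 to 10 and 0.197 in pairs 7, 9 and 10. Cholesterol synthesis genes had a median of 0.20 with 17 of 19 positive (adjusted p = 0.0109; adjusted p = 0.936 with an estimated correlation). It was 0.11 in pairs 1 to 6, 0.30 in pairs 7 to 10 and -0.13 in pairs 7, 9 and 10.

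Genes of the unfolded protein response were lower in GM501 than in SAGE, with a median of -0.34 and 0 of 15 members positive (adjusted p = 1.8e-05). An estimated correlation gave an adjusted p of 0.676. Targets of ATF4, the activator of the amino acid response, had a median of -0.11 with 6 of 33 positive (adjusted p = 0.00602). With an estimated correlation the adjusted p was 0.936. In pairs 1 to 6 their medians were -0.38 and -0.39 (adjusted p = 6.42e-07 each; adjusted p = 0.798 for both with an estimated correlation). In pairs 7 to 10 they were 0.063 and 0.16 (adjusted p = 0.817 and 0.173), and for the unfolded protein response the mean, -0.052, and the test's direction differed in sign from that median. Pairs 7 to 10 also shifted the cell cycle and DNA methylation lists, with medians of 0.467 and 0.475 (adjusted p = 5.22e-05 and 0.000607; adjusted p = 0.929 for both with an estimated correlation). Without pair 8 these were 0.148 and 0.145 and did not pass (adjusted p = 0.148 and 0.298). Adjusted over the list alone, 1 epiblast gene, 1 gene of ribosome biogenesis and 1 gene of the hypoxia response passed; fry gave an adjusted p of 0.995 for every list.

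limma called 0 of 18087 genes, with 695 at an unadjusted p under 0.05 where 904 would fall by chance, and 664 with trend and robust fitting, 878 with array weights and 225 without the pairs, each with 0 called. The median 95% confidence interval of a gene reached 0.324 to each side. A test of whether the effect of medium differed between pairs 1 to 6 and 7 to 10 called 0 genes (1422 at an unadjusted p under 0.05, smallest adjusted p 0.543).

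The second comparison set GM501 twins against undivided KSOM(aa) controls, to ask how blastocysts grown from single blastomeres in a clinical medium differ from undisturbed embryos. At the preset correlation the cholesterol synthesis list was higher in GM501 twins, and the lists of ATF4 targets and the trophectoderm were lower. With an estimated correlation only the trophectoderm passed, at an adjusted p of 0.00509, beside an adjusted p of 0.2 for the other lists. By fry, which sets no list against other genes, trophectoderm, cholesterol synthesis and ATF4 targets had adjusted p of 1.74e-06, 0.000706 and 0.00678. Within pairs 7 to 10 fry gave 0.00138, 5.23e-05 and 0.48 in the same order. Idi1, the isopentenyl diphosphate isomerase of the sterol pathway (chromosome 13, 8885606 to 8892396), rose by 2.03 ± 0.22 log2 units (SE, n = 10 each; adjusted p = 4.78e-05), in 10 of 10 twins. Slc7a8, an amino acid transporter (chromosome 14, 54722215 to 54781886), fell by 3.12 ± 0.54 (adjusted p = 0.0029), with 0 of 10 twins above the controls' median. With pairs 7 to 10 alone these differences were 1.97 ± 0.30 (adjusted p = 0.00687) and -2.29 ± 0.64 (adjusted p = 0.0978).

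Bhmt, a betaine-homocysteine methyltransferase, rose by 2.79 ± 0.59 and Il1rn, the interleukin-1 receptor antagonist, by 2.25 ± 0.53 (adjusted p = 0.00938 and 0.0153), in 9 and 10 of 10 twins. Pde8a, a cAMP phosphodiesterase, rose by 1.81 ± 0.31 in 10 of 10 twins (adjusted p = 0.00265). Csta2, Guca1a and the arylamine acetyltransferases Nat1 and Nat2 rose by 1.84 ± 0.42 for Nat1 to 2.40 ± 0.64 for Csta2, in 8 to 10 of 10 twins. Alppl2, an alkaline phosphatase, fell by 3.00 ± 0.58, and Trpv5, a calcium channel, fell by 2.70 ± 0.47 (adjusted p = 0.00606 and 0.00322). Slc7a5, a transporter of large neutral amino acids, fell by 2.57 ± 0.57 (adjusted p = 0.0124), and each of the 3 genes had 0 or 1 of 10 twins above the controls' median. Usf2 and Nynrin fell by 2.41 ± 0.57 and 2.36 ± 0.54. Guca1a differed by 3.03 ± 0.47 in pairs 7 to 10 (adjusted p = 0.00828). The differences there of Csta2, Usf2, Nynrin and Slc7a5 were 0.73 ± 0.61, -0.34 ± 0.15, -0.37 ± 0.22 and -0.59 ± 0.35 (adjusted p from 0.306 to 0.63). Bhmt, Il1rn, Pde8a, Nat1, Nat2, Alppl2 and Trpv5 were not called there either, at -2.228 ± 0.577 for Trpv5 to 2.635 ± 0.73 for Bhmt (adjusted p from 0.0745 to 0.363).

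Of 19 measured genes of cholesterol synthesis, 9 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.85 (adjusted p = 9.42e-06). The adjusted p was 0.2 with an estimated correlation. Fdps, Sqle and Cyp51, enzymes from farnesyl diphosphate to lanosterol demethylation, rose by 1.21 ± 0.16, 1.40 ± 0.19 and 1.22 ± 0.19 (adjusted p = 0.000334, 0.000396 and 0.00116), each in 10 of 10 twins. Within pairs 7 to 10, 11 of the 19 rose and 15 did adjusted over the list alone, and the median was 1.29 (adjusted p = 6.45e-21). Under an estimated correlation the adjusted p was 0.00847. Without pair 8, 6 rose and the median was 1.21 (adjusted p = 2.65e-16; adjusted p = 0.0326 with an estimated correlation). Mvk, Lss and Hsd17b7 rose in pairs 7 to 10 by 1.70 ± 0.28, 1.60 ± 0.26 and 1.94 ± 0.38 (adjusted p = 0.0106, 0.0093 and 0.0226). Acat3, a cytosolic acetoacetyl-CoA thiolase outside the lists, rose by 1.06 ± 0.15 over all pairs (adjusted p = 0.000566) and 1.03 ± 0.15 in pairs 7 to 10 (adjusted p = 0.00451). Srebf2, which encodes the transcription factor of this pathway, had a difference of -0.73 ± 0.53 over all pairs (adjusted p = 0.309) and 1.22 ± 0.30 in pairs 7 to 10 (adjusted p = 0.0609).

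Of 12 genes of fatty acid synthesis, 2 rose over all pairs (3 adjusted over the list alone), and the list's median of 0.24 did not pass (adjusted p = 0.27). The 2 were the desaturases, Scd1 by 1.23 ± 0.21 (adjusted p = 0.00265) and Fads2 by 0.87 ± 0.26 (adjusted p = 0.0337). Within pairs 7 to 10, 4 rose, and 7 adjusted over the list alone, with a median of 0.88 (adjusted p = 2.63e-10). An estimated correlation gave an adjusted p of 0.00407. Without pair 8, 2 rose and the median was 0.835 (adjusted p = 0.0167 with an estimated correlation). The 4 of pairs 7 to 10 included Fasn, the fatty acid synthase, by 1.79 ± 0.24 (adjusted p = 0.0034) and Acaca, acetyl-CoA carboxylase, by 1.55 ± 0.17 (adjusted p = 0.000565), whose differences over all pairs were 0.24 ± 0.43 and 0.28 ± 0.38. Acsl4, an X-linked acyl-CoA synthetase, rose by 1.61 ± 0.17 over all pairs (adjusted p = 4.78e-05) and by 1.56 ± 0.21 in pairs 7 to 10 (adjusted p = 0.0025). Of 18 genes of lipid uptake, storage and oxidation, 1 rose and 6 fell (2 and 9 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.0144; adjusted p = 0.219 with an estimated correlation). It was 0.0035 in pairs 7 to 10 (adjusted p = 0.969).

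**Figure D2:**
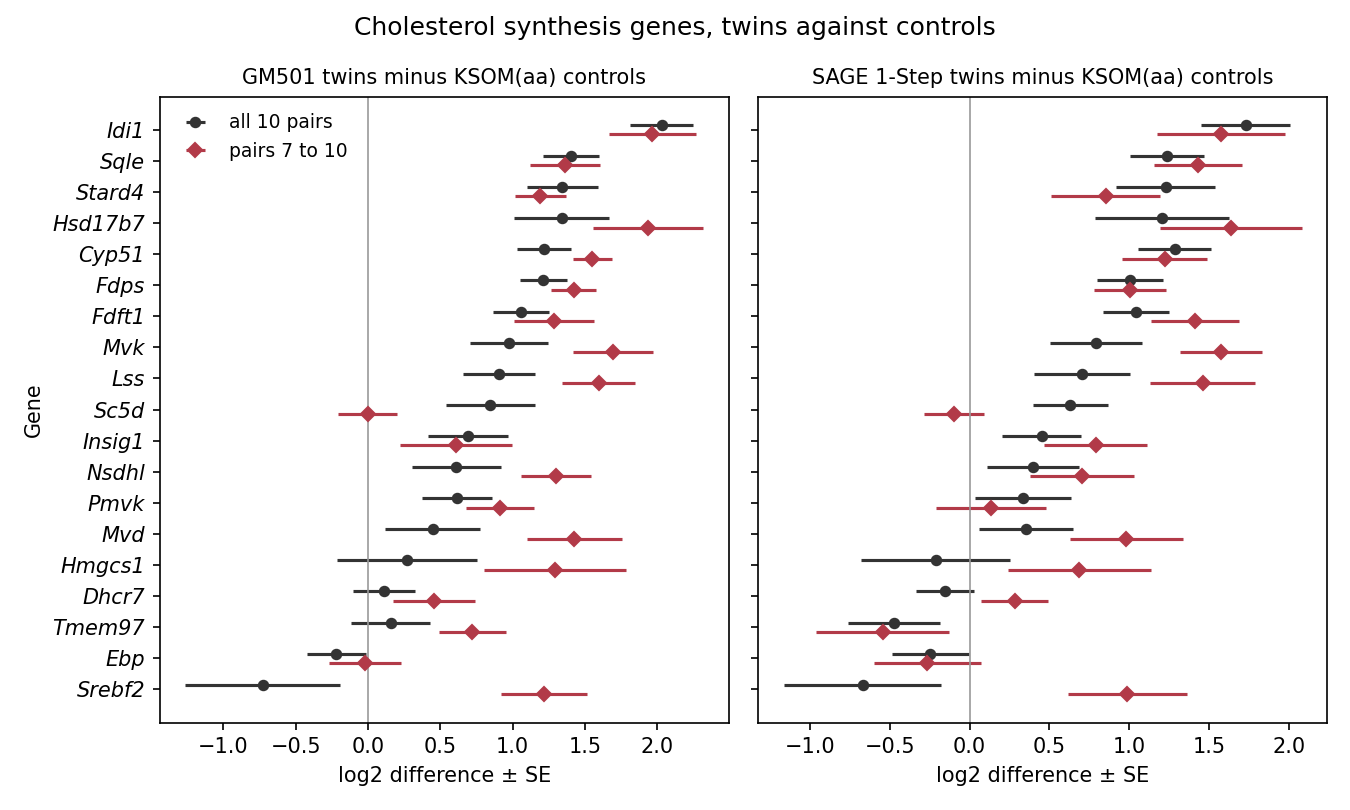
Log2 difference ± SE (horizontal) of each measured cholesterol synthesis gene (vertical) between twins and controls, for all 10 pairs and for pairs 7 to 10, in GM501 (left) and SAGE 1-Step (right). Idi1 lies at 2.03 and 1.73 with all pairs, and Srebf2 lies below 0 with all pairs and above 0 with pairs 7 to 10 in both media.

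Trophectoderm genes fell as a list in GM501 twins, 11 of 18 falling and 0 rising (12 and 0 adjusted over the list alone), with a median of -0.48 (adjusted p = 1.1e-07). This was the only list called with an estimated correlation (adjusted p = 0.00509). With arrays centred on their medians its median was -0.722 (adjusted p = 3.82e-06; adjusted p = 0.537 with an estimated correlation). Gata2, at chromosome 6, 88193891 to 88207032, fell by 0.70 ± 0.11, Tfap2c by 0.73 ± 0.14, Tead4 by 0.82 ± 0.21 and Krt18, a keratin of the outer epithelium, by 0.38 ± 0.097 (adjusted p from 0.00139 to 0.0206). Cdx2 fell by 0.47 ± 0.15 (adjusted p = 0.0439) with 1 of 10 twins above the controls' median. The median in pairs 7 to 10 was -0.39 (adjusted p = 1.02e-05; adjusted p = 0.0375 with an estimated correlation). There 1 gene fell, and 6 did adjusted over the list alone, with Gata2 falling by 0.63 ± 0.12 (adjusted p = 0.018). Without pair 8, 1 gene fell adjusted over the list alone, and the median was -0.288 (adjusted p = 3.75e-05; adjusted p = 0.0766 with an estimated correlation).

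Genes of cavitation and junctions fell in 10 of 18 cases and rose in 0 (12 and 0 adjusted over the list alone), with a median of -0.76 (adjusted p = 1.1e-07). With an estimated correlation the adjusted p was 0.2. The water channel Aqp3 fell by 2.09 ± 0.45, the tight junction gene Cldn4 by 2.32 ± 0.58 and Cdh1, which encodes E-cadherin, by 1.03 ± 0.28 (adjusted p = 0.0106, 0.0189 and 0.0263), with 0, 1 and 1 of 10 twins above the controls' median. The shift was not found in pairs 7 to 10, where the list's median was -0.037 (adjusted p = 0.903) and the differences of Cldn4 and Cdh1 were -0.10 ± 0.19 and -0.069 ± 0.16. In the primitive endoderm list, 6 of 16 genes fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.46 (adjusted p = 4.41e-06; adjusted p = 0.2 with an estimated correlation). It was -0.15 in pairs 7 to 10 (adjusted p = 0.225). Lama1 and Lamc1, laminin chains of the basement membrane, fell by 2.65 ± 0.56 and 2.22 ± 0.64, and the endocytic receptor Cubn fell by 2.91 ± 0.68 (adjusted p = 0.00964, 0.0308 and 0.015). None of the 3 was called in pairs 7 to 10, at -0.865, 0.042 and -1.637 (adjusted p = 0.472, 0.978 and 0.437), so that Lamc1 turned there, with 0.521 without pair 8. Gata6 differed by -0.096 ± 0.21 (adjusted p = 0.742).

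The epiblast list had 1 gene that rose and 3 that fell among 19, with a median of -0.26 (adjusted p = 0.019; adjusted p = 0.351 with an estimated correlation) and 0.07 in pairs 7 to 10 (adjusted p = 0.72). Pou5f1, Nanog and Sox2 differed by -0.69 ± 0.29, -1.04 ± 0.51 and -0.56 ± 0.31 (adjusted p from 0.0999 to 0.187), and by 0.28 ± 0.21, 0.25 ± 0.39 and 0.059 ± 0.39 in pairs 7 to 10. Targets of Hippo signalling did not pass, with a median of -0.042 (adjusted p = 0.206).

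Of 33 targets of ATF4, 19 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of -1.02 (adjusted p = 8.89e-14). The adjusted p was 0.2 with an estimated correlation. Slc3a2, the partner chain of amino acid transporters, fell by 1.70 ± 0.32, and the tRNA synthetase genes Wars and Gars by 1.91 ± 0.36 and 1.68 ± 0.36 (adjusted p = 0.00458, 0.00502 and 0.0102), each with 0 of 10 twins above the controls' median. For pairs 7 to 10 the median was -0.21 (adjusted p = 0.0288; adjusted p = 0.752 with an estimated correlation), 1 gene rose and 1, Slc3a2, fell by 0.56 ± 0.12 (adjusted p = 0.0308). Without pair 8 the list's median was -0.0113 and did not pass (adjusted p = 0.867). The unfolded protein response had 7 of 15 genes falling and 0 rising (10 and 0 adjusted over the list alone), with a median of -0.56 (adjusted p = 4.41e-06; adjusted p = 0.2 with an estimated correlation). The median in pairs 7 to 10 was -0.19 (adjusted p = 0.0492; adjusted p = 0.752 with an estimated correlation), and -0.21 without pair 8, where it did not pass (adjusted p = 0.433). Sel1l, of protein degradation in the endoplasmic reticulum, fell by 0.86 ± 0.15 and Xbp1 by 1.02 ± 0.25, and Sel1l also in pairs 7 to 10, by 0.87 ± 0.19 (adjusted p = 0.0382).

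In energy metabolism, 6 of 17 glycolysis genes and 5 of 15 genes of the tricarboxylic acid cycle fell and 0 rose (7 and 8 falling and 1 and 0 rising adjusted over the list alone), with medians of -0.56 and -0.42 (adjusted p = 6.02e-05 and 1.2e-05; adjusted p = 0.2 with an estimated correlation for both). The glucose transporter Slc2a3 fell by 1.71 ± 0.25 and Hk2, a hexokinase, fell by 1.18 ± 0.36 (adjusted p = 0.000632 and 0.036). Ogdh, of the 2-oxoglutarate dehydrogenase, fell as well (adjusted p = 0.0106). Pairs 7 to 10 gave medians of -0.003 and -0.086 (adjusted p = 0.446 and 0.279), and Slc2a3 fell there by 0.84 ± 0.15 (adjusted p = 0.0139). Oxidative phosphorylation, with 46 genes measured, had 1 rising and 7 falling, among them Ndufa9 by 0.55 ± 0.11 (adjusted p = 0.00751). Its median of 0.031 was positive while its mean of -0.032 and the test's direction were negative (adjusted p = 0.304). This list was lower in pairs 7 to 10, with a median of -0.15 (adjusted p = 1.2e-07; adjusted p = 0.431 with an estimated correlation). There 4 genes fell, 9 adjusted over the list alone, with Ndufa9 falling by 0.42 ± 0.082 (adjusted p = 0.0227). Without pair 8, 0 genes fell, 5 adjusted over the list alone, and the median was -0.116 (adjusted p = 2.97e-05; adjusted p = 0.592 with an estimated correlation).

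The oocyte transcript Khdc3, of the maternal subcortical complex (chromosome 9, 73101381 to 73106631), fell by 1.68 ± 0.22 in GM501 twins (adjusted p = 0.000334), with 0 of 10 above the controls' median. Khdc3 also fell in pairs 7 to 10, by 1.20 ± 0.23 (adjusted p = 0.0221). Dppa3, another maternal transcript, rose by 1.16 ± 0.27 (adjusted p = 0.015), with 0.632 in pairs 7 to 10 (adjusted p = 0.333). The oocyte list as a whole did not pass, with 3 rising and 2 falling of 15 and a median of 0.20 (adjusted p = 0.411). The metallothioneins Mt1 and Mt2 rose by 1.74 ± 0.32 and 1.13 ± 0.28, and the oxidative stress genes Sqstm1 and Txnrd1 fell by 1.63 ± 0.25 and 1.11 ± 0.25 (adjusted p from 0.00135 to 0.0171). Their list had 3 of 18 genes rising, 3 falling and a median of -0.054 (adjusted p = 0.0907). The list had 0 genes called in pairs 7 to 10, where Mt1, Mt2, Sqstm1 and Txnrd1 differed by 0.734, 0.537, -1.032 and -0.321 (adjusted p from 0.102 to 0.527). Ndrg1, of the hypoxia list, fell by 1.12 ± 0.14 over all pairs and by 0.95 ± 0.19 in pairs 7 to 10 (adjusted p = 0.000178 and 0.0221). Ribosome biogenesis and the cell cycle had 4 of 28 and 3 of 30 genes falling and 0 rising (5 and 0 falling adjusted over the list alone), with medians of -0.43 and -0.30 (adjusted p = 0.000131 and 0.000204). Under an estimated correlation the adjusted p were 0.362 and 0.383. Both medians were positive in pairs 7 to 10, at 0.18 and 0.20 (adjusted p = 0.00424 and 0.00175). An estimated correlation gave an adjusted p of 0.72 and 0.702.

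limma called 2493 of 18087 genes, 1232 higher and 1261 lower in GM501 twins, with 1578 changed at least 1.5-fold; pairs 7 to 10 gave 239 (135 higher, 104 lower), of which 86 were called with the same sign over all pairs, and 75 were called without pair 8. Of 51 genes named here and called over all pairs, 18 were called in pairs 7 to 10 and 9 in pairs 7, 9 and 10. The 18 include Acat3, Mvk, Lss, Hsd17b7 and Acsl4, which were named after their values were seen. The median difference of all genes was 0.114 as deposited, -0.040 after quantile normalization again and -0.125 with arrays centred on their medians, so that the rises stand against a general shift of 0.114. The latter scalings gave 509 higher and 1922 lower, and 258 higher and 2285 lower. None of the named genes called over all pairs changed direction under either scaling, nor did a called list with centred arrays.

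**Figure D3:**
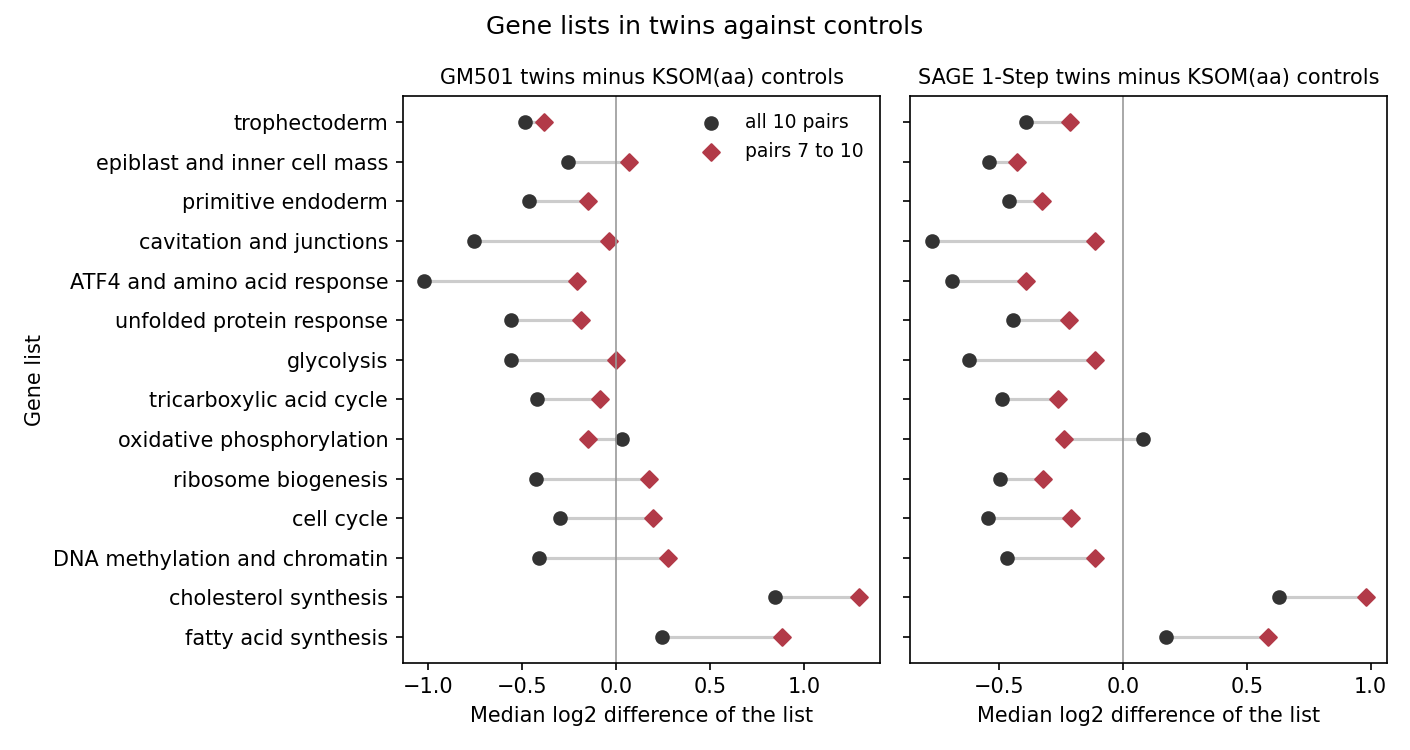
Median log2 difference (horizontal) of 14 fixed gene lists (vertical) between twins and controls, for all 10 pairs (circles) and pairs 7 to 10 (diamonds), in GM501 (left) and SAGE 1-Step (right). Cholesterol synthesis lies at 0.85 and 1.29 in GM501 and at 0.63 and 0.98 in SAGE, while most lists that lie below 0 with all pairs lie closer to 0, or above it, with pairs 7 to 10.

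The third comparison put the same question to SAGE 1-Step twins. Idi1 rose by 1.73 ± 0.28 (SE, n = 10 each; adjusted p = 0.00364), in 9 of 10 twins, with 1.57 ± 0.40 in pairs 7 to 10 (adjusted p = 0.0737). Rcor3, of a corepressor complex, rose by 2.24 ± 0.58, Mt1 by 1.64 ± 0.25, Pde8a by 1.62 ± 0.30 and Cryab, a small heat shock protein gene, by 1.59 ± 0.35 (adjusted p = 0.0189, 0.00213, 0.00656 and 0.0111), in 8 to 10 of 10 twins. Csta2, Il1rn and Slco4c1 rose by 2.13 ± 0.67, 1.82 ± 0.50 and 1.60 ± 0.48. Cubn fell by 2.85 ± 0.66, Alppl2 fell by 2.69 ± 0.54, Slc7a8 fell by 2.63 ± 0.58 and Lama1 fell by 2.61 ± 0.53 (adjusted p = 0.0129, 0.00799, 0.0111 and 0.00855), with 0 or 1 of 10 twins above the controls' median. Aqp3, Lamc1, Cldn4 and Ttyh2 fell by 2.32 ± 0.51 for Ttyh2 to 2.43 ± 0.54 for Aqp3. None of these 16 genes was called in pairs 7 to 10; Cubn differed there by -2.97 ± 0.97, Mt1 by 0.86 ± 0.22 and Cldn4 by -0.12 ± 0.23 (adjusted p = 0.135, 0.0729 and 0.85).

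Cholesterol synthesis had 6 of 19 genes rising and 0 falling in SAGE twins (9 and 0 adjusted over the list alone), with a median of 0.63 (adjusted p = 0.00403). With an estimated correlation the adjusted p was 0.413. By fry, cholesterol synthesis, trophectoderm and ATF4 targets had adjusted p of 0.0153, 0.00408 and 0.00458 over all pairs. These were 0.0375, 0.119 and 0.1 in pairs 7 to 10. Cyp51 rose by 1.29 ± 0.23, Sqle by 1.24 ± 0.23 and Fdft1, the squalene synthase, by 1.04 ± 0.21 (adjusted p = 0.00523, 0.00678 and 0.00788), in 9, 10 and 10 of 10 twins. All 3 rose again in pairs 7 to 10, by 1.22 ± 0.27, 1.43 ± 0.28 and 1.41 ± 0.28 (adjusted p = 0.0487, 0.0288 and 0.0293). Acat3 and Mvk rose there by 1.16 ± 0.15 and 1.58 ± 0.26 (adjusted p = 0.00733 and 0.027). The list's median there was 0.98, with 4 rising and 12 adjusted over the list alone (adjusted p = 1.64e-10). The adjusted p was 0.285 with an estimated correlation. Without pair 8, 7 rose and the median was 1.28 (adjusted p = 1.44e-18; adjusted p = 0.0325 with an estimated correlation). Scd1, of fatty acid synthesis, rose by 1.15 ± 0.18 over all pairs and by 1.28 ± 0.25 in pairs 7 to 10 (adjusted p = 0.00226 and 0.0293). Its list had a median of 0.18 over all pairs (adjusted p = 0.503) and 0.59 in pairs 7 to 10 (adjusted p = 1.49e-05; adjusted p = 0.285 with an estimated correlation), where leaving out pair 8 gave 0.724 (adjusted p = 0.0325 with an estimated correlation). Srebf2 differed by -0.67 ± 0.49 over all pairs and by 0.99 ± 0.38 in pairs 7 to 10 (adjusted p = 0.305 and 0.192).

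Epiblast genes fell in SAGE twins, 8 of 19 falling and 0 rising (9 and 0 adjusted over the list alone), with a median of -0.54 (adjusted p = 1.07e-05). Under an estimated correlation the adjusted p was 0.234. Zfp42, a marker of pluripotent cells, fell by 1.58 ± 0.27, Nanog by 1.54 ± 0.35, Pou5f1 by 1.14 ± 0.25 and Sox2 by 1.03 ± 0.22 (adjusted p = 0.0045, 0.0122, 0.011 and 0.00956), each with 0 of 10 twins above the controls' median. The list's median in pairs 7 to 10 was -0.43 (adjusted p = 0.000103; adjusted p = 0.329 with an estimated correlation). There 0 genes were called and 5 fell adjusted over the list alone, and Nanog and Sox2 differed by -1.70 ± 0.47 and -1.12 ± 0.33 (adjusted p = 0.0883 and 0.102). Without pair 8, whose SAGE twin stood apart, the median was -0.27 (adjusted p = 0.0767) and 0 genes fell adjusted over the list alone. Trophectoderm genes fell in 7 of 18 cases (8 adjusted over the list alone), with a median of -0.39 (adjusted p = 3.15e-05; adjusted p = 0.234 with an estimated correlation). Tead4 fell by 0.95 ± 0.19, Tfap2c by 0.76 ± 0.18, Cdx2 by 0.71 ± 0.14 and Gata2 by 0.61 ± 0.14, and the median in pairs 7 to 10 was -0.21 (adjusted p = 0.123). Primitive endoderm genes fell in 7 of 16 cases (9 adjusted over the list alone), with a median of -0.46 (adjusted p = 1.77e-06; adjusted p = 0.234 with an estimated correlation). That of pairs 7 to 10 was -0.33 (adjusted p = 0.00836; adjusted p = 0.644 with an estimated correlation), and -0.157 without pair 8 (adjusted p = 0.511). Gata6 differed by -0.43 ± 0.20 (adjusted p = 0.126).

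Cavitation and junction genes fell in 9 of 18 cases and rose in 0 (12 and 0 adjusted over the list alone), with a median of -0.77 (adjusted p = 3.7e-06; adjusted p = 0.236 with an estimated correlation). It was -0.11 in pairs 7 to 10 (adjusted p = 0.956). Atp1b1, a chain of the sodium pump, fell by 1.09 ± 0.25 (adjusted p = 0.0135) and differed by -0.56 ± 0.27 in pairs 7 to 10. Of 33 targets of ATF4, 17 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.69 (adjusted p = 1.33e-10; adjusted p = 0.234 with an estimated correlation). Within pairs 7 to 10 it was -0.39 (adjusted p = 0.000116). An estimated correlation gave an adjusted p of 0.597, and without pair 8 the median was -0.216 (adjusted p = 0.119). Wars fell by 1.98 ± 0.35, Slc3a2 by 1.51 ± 0.26 and Mars1 by 1.12 ± 0.23 (adjusted p = 0.00521, 0.0045 and 0.00799). None of the 3 was called in pairs 7 to 10, where Slc3a2 differed by -0.83 ± 0.20 (adjusted p = 0.0575). The unfolded protein response had 4 of 15 genes falling and a median of -0.44 (adjusted p = 0.0111; adjusted p = 0.413 with an estimated correlation), with -0.22 in pairs 7 to 10 (adjusted p = 0.411).

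Glycolysis had 10 of 17 genes falling and 1 rising in SAGE twins, and the tricarboxylic acid cycle 3 of 15 falling and 0 rising (12 and 9 falling and 2 and 0 rising adjusted over the list alone), with medians of -0.62 and -0.49 (adjusted p = 0.000127 and 8.12e-05; adjusted p = 0.236 with an estimated correlation for both). Slc2a3 fell by 1.68 ± 0.34, Hk2 by 1.38 ± 0.39 and Ogdh by 1.48 ± 0.34 (adjusted p = 0.00855, 0.0261 and 0.0128). The medians in pairs 7 to 10 were -0.11 and -0.26 (adjusted p = 0.515 and 0.0015; adjusted p = 0.604 with an estimated correlation for the latter). Without pair 8 the latter was -0.149 and did not pass (adjusted p = 0.511). Ndufv1, of respiratory complex I, fell by 0.84 ± 0.23 (adjusted p = 0.0233). Its list, oxidative phosphorylation, had a positive median of 0.083 over all pairs beside a negative mean of -0.0092 and test direction (adjusted p = 0.674). Pairs 7 to 10 gave a median of -0.24 (adjusted p = 4.2e-08; adjusted p = 0.285 with an estimated correlation), and 2 genes fell and 11 did adjusted over the list alone, or 4 without pair 8. Khdc3 fell by 1.73 ± 0.20 over all pairs and by 1.32 ± 0.22 in pairs 7 to 10 (adjusted p = 0.00044 and 0.0274). Gdf9, an oocyte growth factor, rose by 0.56 ± 0.11 (adjusted p = 0.00711) and differed by 0.47 ± 0.12 in pairs 7 to 10.

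Ribosome biogenesis, the cell cycle and DNA methylation and chromatin had 9 of 28, 9 of 30 and 6 of 22 genes falling and 0 rising in SAGE twins (13, 10 and 8 falling adjusted over the list alone). Their medians were -0.50, -0.55 and -0.47 (adjusted p = 2.1e-07, 2.54e-05 and 3.27e-05; adjusted p = 0.236, 0.351 and 0.236 with an estimated correlation). Among them, Rrp9 and Fbl, of ribosomal RNA processing, fell by 0.95 ± 0.13 and 0.68 ± 0.13, and the replication genes Mcm2 and Mcm5 by 1.53 ± 0.37 and 1.14 ± 0.33. The mitotic kinase gene Aurka fell by 1.28 ± 0.39, Trim28 by 1.80 ± 0.41 and the DNA methyltransferase gene Dnmt3b by 1.16 ± 0.34 (adjusted p of the 7 genes from 0.00175 to 0.0331). Pairs 7 to 10 gave medians of -0.32, -0.21 and -0.11 (adjusted p = 0.0015, 0.13 and 0.392; adjusted p = 0.644 with an estimated correlation for the first). Leaving out pair 8, whose SAGE twin stood apart, turned all 3 positive, at 0.0177, 0.0275 and 0.174 (adjusted p = 0.525, 0.362 and 0.0465; adjusted p = 0.502 with an estimated correlation for the last). Mt2 rose by 1.05 ± 0.22, and Txnrd1 and Sqstm1 fell by 1.30 ± 0.21 and 1.35 ± 0.31, in an oxidative stress list with 2 of 18 genes rising, 5 falling and a median of -0.077 (adjusted p = 0.186).

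limma called 2917 of 18087 genes, 1355 higher and 1562 lower in SAGE twins, and 147 with pairs 7 to 10 (51 higher, 96 lower), of which 36 were called with the same sign over all pairs. Of 49 genes named here and called over all pairs, 6 were called in pairs 7 to 10 and 6 in pairs 7, 9 and 10. Those called in pairs 7 to 10 include Acat3, which was named after its values were seen. The median of all genes was 0.111 as deposited, -0.046 after quantile normalization again (498 higher, 2258 lower) and -0.134 with centred arrays (260 higher, 3126 lower); with the Y-linked score and Xist as covariates 1376 genes were called.

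Averaging co-twins set both media against the controls with 1 value per embryo. Idi1 rose by 1.88 ± 0.23 (SE, n = 10 each), Acsl4 by 1.60 ± 0.20 and Mt1 by 1.69 ± 0.27 (adjusted p = 0.000184, 0.000284 and 0.0014), in 10 of 10 pairs. The other large rises were those of Xlr, Csta2, Bhmt, Il1rn and Pde8a, from 1.71 ± 0.28 for Pde8a to 2.48 ± 0.86 for Xlr. Cubn fell by 2.88 ± 0.62, Slc7a8 by 2.87 ± 0.51, Alppl2 by 2.85 ± 0.50 and the zinc transporter gene Slc39a4 by 2.28 ± 0.34 (adjusted p = 0.007, 0.00274, 0.00249 and 0.000665), with 0 of 10 pairs above the controls' median. Lama1, Slc7a5, Cldn4 and Lamc1 fell by 2.30 ± 0.56 for Lamc1 to 2.63 ± 0.53 for Lama1. Of these 16 genes, Idi1 and Acsl4 were called in pairs 7 to 10, at 1.77 ± 0.33 and 1.67 ± 0.28 (adjusted p = 0.0286 and 0.0175).

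Cholesterol synthesis had 10 of 19 genes rising and 0 falling against the controls (11 and 0 adjusted over the list alone), with a median of 0.74 (adjusted p = 0.000215). With an estimated correlation the adjusted p was 0.258. By fry, cholesterol synthesis, trophectoderm and ATF4 targets had adjusted p of 0.00195, 8.09e-05 and 0.00306 over all pairs. These were 0.000918, 0.0138 and 0.227 in pairs 7 to 10. For pairs 7 to 10, 8 rose and 13 did adjusted over the list alone, with a median of 1.10 (adjusted p = 1.67e-19; adjusted p = 0.0223 with an estimated correlation). There Cyp51, Sqle and Fdps rose by 1.39 ± 0.19, 1.40 ± 0.24 and 1.21 ± 0.18 (adjusted p = 0.00642, 0.0197 and 0.00819). Fatty acid synthesis, with a median of 0.21 over all pairs (adjusted p = 0.355), had 4 of 12 genes rising and a median of 0.76 in pairs 7 to 10 (adjusted p = 3.89e-10). The adjusted p was 0.0223 with an estimated correlation. Trophectoderm genes fell in 11 of 18 cases, with a median of -0.46 (adjusted p = 1.26e-06; adjusted p = 0.104 with an estimated correlation) and -0.30 in pairs 7 to 10 (adjusted p = 0.000203). Under an estimated correlation the adjusted p was 0.232. Cdx2, Pou5f1, Nanog and Sox2 fell by 0.59 ± 0.12, 0.92 ± 0.25, 1.29 ± 0.35 and 0.79 ± 0.24, and Gata6 differed by -0.26 ± 0.15 (adjusted p = 0.163); in pairs 7 to 10 none of the 5 was called. Khdc3 fell by 1.70 ± 0.20 over all pairs and 1.26 ± 0.22 in pairs 7 to 10, Slc2a3 by 1.70 ± 0.28 and 0.78 ± 0.16, and Ndufa9 by 0.54 ± 0.12 and 0.49 ± 0.085 (adjusted p in pairs 7 to 10 of 0.0206, 0.0383 and 0.0202).

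limma called 4625 genes in this comparison, 2560 higher and 2065 lower, and 132 in pairs 7 to 10 (69 higher, 63 lower), with 40 called without pair 8. Of 26 genes named here and called over all pairs, 8 were called in pairs 7 to 10 and 5 in pairs 7, 9 and 10. With quantile normalization again the split was 826 higher and 2952 lower, and with centred arrays 454 higher and 3802 lower, at medians of all genes of 0.114, -0.042 and -0.128.

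Across genes, which are not independent replicates, the log2 differences of both media from the controls correlated with r = 0.906 and a covariance of 0.203. The same 10 controls enter both; simulated groups without any effect gave r = 0.587 and a covariance of 0.0294, a covariance difference of 0.174, and controls divided 5 and 5 gave r = 0.793. In pairs 7 to 10, r was 0.455 with a covariance of 0.054, against 0.381 and 0.0258 in simulated groups, a covariance difference of 0.0282, and r was 0.303 with divided controls. Both media had 602 genes higher and 878 lower in common, and 24 and 18 in pairs 7 to 10, with the same controls in both. Most of the 24 were small RNA or predicted genes. Some of these had identical values, such as Rn7s1 and Rn7s2 at 0.676 in GM501 and 0.766 in SAGE, so the 24 are not separate signals. Khdc3, Ndufa9, Cyp51, Sqle, Fdft1, Mvk and Acat3 were among the genes shared in pairs 7 to 10.

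The pairs allow a further question, how far the embryo of origin sets the transcriptome of a twin whatever its medium. Sex-linked genes varied most between pairs: Eif2s3y on Y (1010562 to 1049134), a translation factor, had F = 140, and Xist on X (103460373 to 103483233), the RNA of X inactivation, F = 132 (adjusted p = 1.16e-06 each). Xist lay on the same side of a log2 of 12 in both co-twins of 10 of 10 pairs. The mean absolute difference between co-twins was 0.779 log2 units for Xist and 0.25 for Eif2s3y, against 5.42 and 2.09 between permuted partners (permutation p = 0.00034 and 5e-05). Xist was above 12 in 5 of 10 GM501 twins, 5 of 10 SAGE twins and 7 of 10 controls.

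**Figure D4:**
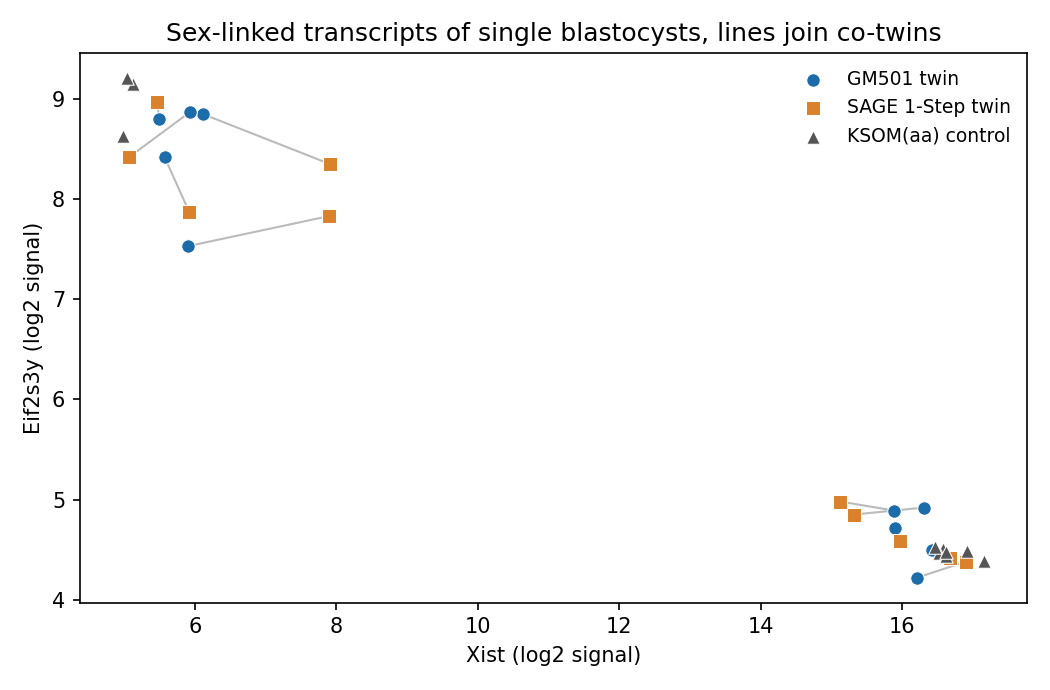
Xist (log2 signal, horizontal) against Y-linked Eif2s3y (log2 signal, vertical) in each of the 30 blastocysts, with lines joining co-twins. All 10 pairs keep to 1 side of a log2 of 12 for Xist, and co-twins differ in Eif2s3y by at most 0.55.

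Other genes with a strong pair effect were Sly, a Y-linked gene of the germ line (F = 88), Cwc22, a splicing factor (58.1), Baiap2l1 (45.2), the dynein heavy chain gene Dync1h1 (43.4), Y-linked Uty (42.3), Agrn (40.4) and Srcap (36.8), at adjusted p from 4.3e-06 to 0.000114. Y-linked Kdm5d had F = 6.54 (adjusted p = 0.0147). Within pairs 1 to 6, Eif2s3y (F = 153), Sly (141), Xist (94.6), Baiap2l1 (54.1) and Uty (47.9) were among the genes called. Those called within pairs 7 to 10 included Xist (499), Eif2s3y (137), Uty (73.6) and Cwc22 (70). Dync1h1, Agrn, Srcap and Kdm5d were called in neither set. limma's F test called 4778 of 18087 genes over all pairs, 393 of them among the 1138 tested genes on X and Y. Within pairs 1 to 6 it called 44, 27 of them on X and Y, and within pairs 7 to 10 it called 12, 3 of them on X and Y. Some of these were predicted genes with the same F. Examples are Gm20885 and Gm21191 on Y at 143 in pairs 1 to 6. In pairs 7 to 10, Gm13693 and Gm13694 on chromosome 2 had 133. The 44 and the 12 are therefore not all separate signals.

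Over all genes kept, co-twins in different media correlated with a mean r of 0.445 ± 0.178 (SD, 10 pairs), against -0.048 between unrelated twins in different media (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). In 7 of 10 pairs the co-twin was the best match. Centred and permuted within pairs 1 to 6 and within pairs 7 to 10, mean r was 0.204 against -0.0491 (permutation p = 5e-05), with the co-twin best in 9 of 10 pairs. After regression on the Y-linked score and Xist and without X and Y genes it was 0.155 ± 0.189 (SD, 10 pairs) against -0.0376 (permutation p = 0.0063), with the co-twin best in 5 of 10 pairs and a lowest r of -0.263.

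**Figure D5:**
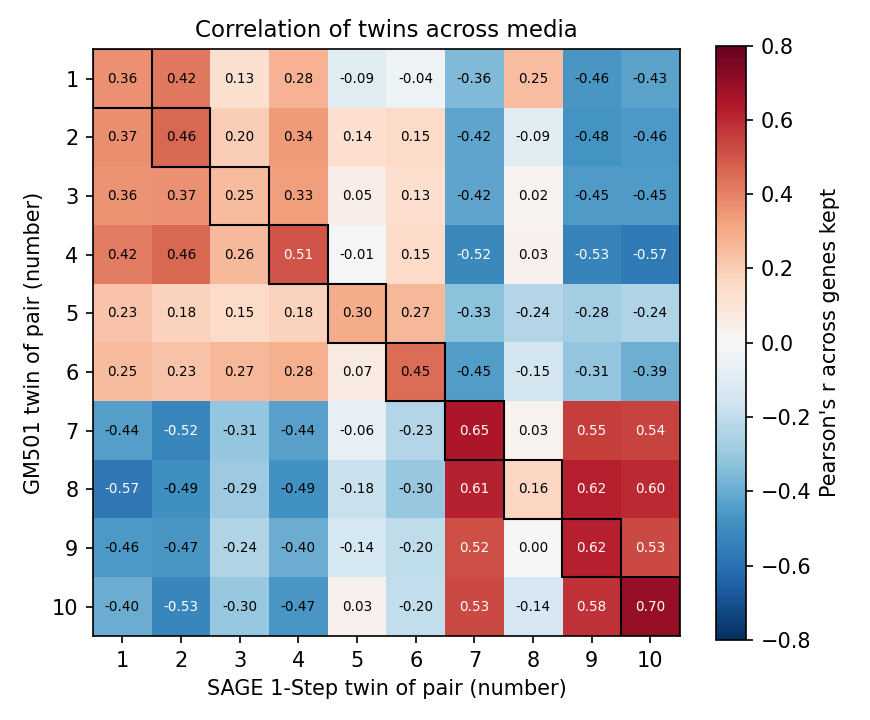
Pearson's r across genes between each GM501 twin (vertical, pair number) and each SAGE 1-Step twin (horizontal, pair number), each gene centred within its medium; boxes mark co-twins. Boxed values run from 0.163 to 0.696, and pairs 1 to 6 and pairs 7 to 10 form blocks.

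Twins also differed in how alike the embryos of a group were. The mean distance of a blastocyst to the others of its group was 0.655 ± 0.081 log2 units in GM501 twins and 0.661 ± 0.107 in SAGE twins, against 0.398 ± 0.030 in controls (SD, n = 10 each). Each medium differed from controls at a permutation adjusted p of 4.5e-05. The media did not differ (exact sign flip p = 0.873). In pairs 7 to 10 the distances were 0.475 ± 0.033 and 0.583 ± 0.179 (SD, n = 4 each; exact permutation adjusted p = 0.0015 against controls). Without pair 8 they were 0.487 ± 0.022 in GM501 and 0.435 ± 0.029 in SAGE (SD, n = 3 each; exact permutation adjusted p = 0.0105 and 0.131).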

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

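The test of signal range in pairs 1 to 6, the other groupings of the GM501 and SAGE twins, and every value from pairs 1 to 6 or pairs 7 to 10 alone were chosen only after the result had been seen.

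Among 246 groups of 10 values, 10 held a blastocyst far from the others, where chance alone gives about 1 in 20 groups. Gata6 was 10.45 in the GM501 twin of pair 1, whose nearest neighbour was 11.5. Sox2 was 8.92 in the GM501 twin of pair 10, with the next at 7.43. Idi1 was 8.24 in the SAGE twin of pair 8, the twin that stands apart in its set, with the next at 9.5. Kdm5d was 7.57 in the SAGE twin of pair 9, with the next at 6.01. Among controls, Cldn4 was 15.01 and Hk2 10.58 in control 6, with the next at 15.81 and 9.79. Mars1 was 11.41 and Mt2 11.18 in control 8, with the next at 11.82 and 10.73. Ttyh2 was 10.15 in control 4 and Txnrd1 9.71 in control 9, with the next at 11.86 and 8.91.

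Signal outside the named genes also differed. Of 14948 clusters without a single named gene, 1532 were higher and 217 lower in GM501 twins than in controls, and 2113 were higher and 243 lower in SAGE twins. In pairs 7 to 10 the counts of higher clusters were 144 and 71. Array medians were 4.88 and 4.89 in GM501 and SAGE twins, beside 4.64 in controls. For named genes in GM501, centring arrays on their medians turned 1232 higher and 1261 lower into 258 and 2285. The cluster counts are given for deposited values alone, so the excess of higher clusters cannot be told apart from this general shift. Between media, limma called 0 of these clusters, with 532 at an unadjusted p under 0.05.

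Pairs 1 to 6 lay apart from pairs 7 to 10 and the controls on the first principal component, although no label names a batch. Between these twin sets 8455 of 18087 genes were called, 5334 higher and 3121 lower in pairs 1 to 6. Compression of the signal range, through background or RNA yield, predicts that the difference falls with mean level. Spearman's rho across clusters was only -0.0601, but of 4 equal groups of clusters by level the brightest had a median difference of 0.0888, beside 0.284 to 0.339 in the others, so compression stays open. A developmental lag of these embryos may account for lower lineage genes. In pairs 1 to 6, epiblast and primitive endoderm lists lay at percentiles 1.74 and 0.31 of matched lists. Their shifts passed at the preset correlation (adjusted p = 0.0362 and 0.00424) and not with an estimated correlation (adjusted p = 0.481 and 0.478). Other lists lay as low, with ATF4 targets at percentile 0, ribosome biogenesis at 0.01 and glycolysis at 0.03, while oxidative phosphorylation lay at 98.5. Low places were therefore not particular to lineage genes. The trophectoderm list lay at percentile 5.51 and the oocyte list at 32.9, a place not high as was predicted for a lag. Yet 13 of 15 oocyte genes were higher in pairs 1 to 6 than in pairs 7 to 10. Of them 5 were called higher and 1 lower (fry adjusted p = 0.00315), so this list does not speak plainly against a lag. A lag, compression and an unrecorded batch therefore cannot be told apart here, because neither test decided and no label names a batch. All controls lie with pairs 7 to 10. Any difference from controls that is small in pairs 7 to 10 shares this doubt.

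Cholesterol synthesis genes were higher in twins of both media than in controls at the preset correlation. With an estimated correlation the list had an adjusted p of 0.258 over all pairs and 0.0223 in pairs 7 to 10. The array sets as the whole cause are argued against by pairs 7 to 10, where the list's median was 1.10, above that of all pairs. The sex of the embryos is argued against by a median of 0.711 with the Y-linked score and Xist as covariates. Compressed signal predicts no extreme place among lists matched on mean level, and the list lay at percentile 100. Yet the cavitation list lay at percentile 0 with a median of -0.76, which was -0.0756 in pairs 7 to 10. An extreme place can thus go with a shift nearly absent from pairs 7 to 10. Random lists also draw genes independently, so this place does not decide on compression. The SD of log2 signals across clusters averaged 2.727 in pairs 7 to 10, 2.738 in controls and 2.638 in pairs 1 to 6. The list's median of 1.10 was thus found where the signal range was close to that of controls. For this list, that argues against compression as the whole cause. A response of sterol synthesis to the clinical media or to growth from a single blastomere remains as a hypothesis; the design joins medium, bisection and cell number, so these stay open and untested.

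Co-twins in different media were more alike than unrelated twins. Array sets as the whole cause are argued against by a permutation p of 5e-05 with the pairing permuted within the sets, and sex by a permutation p of 0.0063 after regression on sex-linked genes. A lasting effect of the embryo's genotype or of its history before bisection is a candidate explanation, and neither was tested. Pairs may also have shared a day of culture within the sets, which no label gives.

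Other groupings of the same arrays bear on the counts of genes called. Between media the real count was 0, which each of the 100 of 100 sign groupings reaches whatever the data, so this test says nothing there; the highest other count was 1. Against controls, only the real grouping reached its count, 1 of 100, the smallest share that 100 groupings can give. The counts were 2493 in GM501 twins (highest other 5), 2917 in SAGE twins (highest other 1) and 4625 in both media (highest other 0). These regroupings leave the array sets aside, and all controls lie with pairs 7 to 10. The real grouping keeps all twins of the other set apart from the controls, whereas random groupings can mix them. Over all pairs the test therefore cannot tell a difference from controls from a difference between the sets. Within pairs 7 to 10 and the controls the counts were 239, 147 and 132, and the highest of 99 other groupings gave 13, 1 and 57. For the embryo of origin the real pairing alone, 1 of 100, gave 4778 genes, and the highest other gave 905. Pairings drawn within the array sets gave a median of 2606 and up to 4290, so most of that count follows the sets, and within them 44 and 12 genes were called.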

How the results depend on the processing

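Fits with pairs 1 to 6, pairs 7 to 10, or pairs 7, 9 and 10 alone, the array median as a covariate, and sex covariates for lists were chosen after the data had been seen. Between GM501 and SAGE twins, 0 genes were called under all alternatives run, without the pairs (no replicate block) and without each pair in turn included. All 10 named genes of the pair effect, 42 of 51 in GM501 against controls, 41 of 49 in SAGE and 22 of 26 in both media stayed called under all settings fixed beforehand; none of them reversed there. Over those settings 1711 gene results kept their side of the threshold, 35 lost and 6 gained a call; for lists these were 231, 41 and 1. Over the fits chosen later, 147 gene results kept their side, 303 lost and 9 gained a call and 12 reversed, and for lists these were 193, 35, 22 and 23. With the array median as a covariate, 38 gene results kept their side, 96 lost and 3 gained a call. The unfiltered counts include genes with means under 4.8 log2 units, and why these counts were higher was not tested.

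The count of 2493 in GM501 against controls became 5757 without the filter, 7908 with array weights, 1578 at 1.5-fold or more, 239 with pairs 7 to 10, 75 with pairs 7, 9 and 10, and 99 with the array median as a covariate. For SAGE, 2917 became 7911, 8874, 1794, 147, 124 and 23 in the same order, and 1376 with sex covariates. For both media, 4625 became 12409, 10795, 2188, 132, 40 and 57, and 2992 with the stricter filter. The fewer arrays and the minimum fold lower counts by construction; otherwise the cause was not tested. The pair effect fell from 4778 genes to 44 in pairs 1 to 6, 12 in pairs 7 to 10 and 10 in pairs 7, 9 and 10.

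Control numbers pair nothing by design: with the number as a replicate block the counts were 1373 in GM501 and 1916 in SAGE, and 0 and 2 of 10 twins correlated best with the control of their number. The block changed no other count by over 1.5 times. Correlation of the differences in both media was 0.793 with divided controls and 0.455 in pairs 7 to 10. The spread of SAGE twins exceeded that of controls by 0.0366 in pairs 7, 9 and 10 and no longer passed.

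Lists called with an estimated correlation numbered 0 between media (5 at the preset one), 1 in GM501 (15), 0 in SAGE (14) and 0 in both media (14). At the preset correlation the higher and lower lists between media were 3 and 2, with 6 and 1 in pairs 7 to 10, 2 and 2 in pairs 7, 9 and 10, and 0 and 5 in pairs 1 to 6. Against controls they were 1 and 14 in GM501, 1 and 13 in SAGE and 1 and 13 in both media. Pairs 7 to 10 gave 10 lists (5 and 5), 9 (2 and 7) and 10 (3 and 7), and pairs 7, 9 and 10 gave 7 (5 and 2), 6 (4 and 2) and 6 (3 and 3).

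Some results reversed, and the cause was not tested. In GM501, Lamc1 was 0.042 in pairs 7 to 10 and 0.521 in pairs 7, 9 and 10. In the latter, SAGE gave Csta2 -0.26, Cldn4 0.131, Hk2 0.395, Mcm5 0.062, Aurka 0.037, Trim28 0.092 and Dnmt3b 0.241, and both media gave Cldn4 0.001, Lamc1 0.211 and Pou5f1 0.049. Among list medians between media, pairs 7, 9 and 10 gave ATF4 targets 0.227 and cholesterol synthesis -0.127, pairs 7 to 10 ATF4 targets 0.162, and pairs 1 to 6 the cell cycle -0.102 and ribosome biogenesis -0.114. In GM501 against controls, pairs 7, 9 and 10 gave cavitation 0.00833, cell cycle 0.191, DNA methylation 0.293 and ribosome biogenesis 0.213. Pairs 7 to 10 gave epiblast 0.07, cavitation -0.0365 (test direction reversed), cell cycle 0.196, DNA methylation 0.276, cytosolic ribosomal proteins -0.114 and ribosome biogenesis 0.177. In SAGE, pairs 7, 9 and 10 gave cavitation 0.141, glycolysis 0.0573, lipid uptake 0.0293, p53 targets -0.0143 (test direction reversed), unfolded protein response 0.0573, cell cycle 0.0275, DNA methylation 0.174 and ribosome biogenesis 0.0177.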

Other observations

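Beyond sterol enzymes, other genes were called in both media within pairs 7 to 10, and are named here after their values were seen. Zfp229, a zinc finger gene, rose by 1.09 ± 0.16 in GM501 and 1.28 ± 0.14 in SAGE twins (SE, 4 twins against 10 controls; limma adjusted p = 0.00451 and 0.00432), and Echdc1, an enzyme of fatty acid metabolism, by 1.06 ± 0.21 and 0.97 ± 0.21. Keap1, the inhibitor of the oxidative stress factor NRF2, fell by 0.66 ± 0.11 and 0.58 ± 0.13, and Coq3, of ubiquinone synthesis, by 0.95 ± 0.18 and 1.16 ± 0.19. Rab20 fell by 1.02 ± 0.12 and 0.96 ± 0.14, the lysosomal phospholipase gene Pla2g15 by 0.81 ± 0.10 and 0.66 ± 0.14, and the complex I gene Ndufb9 by 0.44 ± 0.081 and 0.51 ± 0.096. Over all pairs Ndufb9 differed by 0.093 and 0.086 and was not called (adjusted p = 0.659 and 0.71). The Y RNA gene Rny3 rose by 1.49 ± 0.26 and 1.46 ± 0.27, and the U2 copy Rnu2-10 by 1.52 ± 0.30 and 1.99 ± 0.37. Over all pairs Rny3 differed by 0.039 and 0.111 and Rnu2-10 by 0.607 and 0.723, and neither was called (adjusted p from 0.178 to 0.95).

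Cytosolic ribosomal protein genes, with 32 measured, had medians of 0.11 and 0.030 over all pairs in GM501 and SAGE (adjusted p = 0.628 and 0.599). In pairs 7 to 10 they were -0.11 and -0.22 (adjusted p = 0.0109 and 3.57e-08; adjusted p = 0.752 and 0.285 with an estimated correlation), and 0 and 14 genes fell adjusted over the list alone. Without pair 8 they were -0.0268 and -0.188 (adjusted p = 0.433 and 2.52e-06; adjusted p = 0.494 with an estimated correlation for SAGE). Transcripts of the 2-cell stage had medians of 0.46 and 0.37 with 3 and 2 of 8 genes rising (adjusted p = 0.0801 and 0.118). Imprinted genes, with 25 measured, had medians of -0.051 and 0.059, and apoptosis genes -0.14 and -0.14, and neither list passed. Markers of cumulus and granulosa cells, with 5 measured, had medians of 0.23 and 0.18 (adjusted p = 0.27 and 0.269).

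Within pairs 1 to 6, genes outside X and Y that varied between embryos more than between co-twins included Txnip (F = 34.4), a regulator of glucose uptake, Tdgf1 (27.9), of the inner cell mass, and Pcsk6 (26.6), a proprotein convertase that acts on Nodal, at adjusted p of 0.0254, 0.0457 and 0.0495. They were named after their values were seen.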
